A study of Rattus norvegicus with 48 samples.

How the data were processed

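Arrays of pyramidal neurons of CA1 and CA3 and of granule cells of the dentate gyrus (DG), from CON and PR animals, were compared. Per the labels, total RNA was extracted and hybridised to an Affymetrix rat expression array. How the 3 populations were collected and what PR stands for is not given in the sources used here. The deposited values are intensities, 1 per probe set and array, on a linear scale per the labels and the values themselves. The trimmed mean of the deposited intensities, without the lowest and highest 2% of values, lay between 149.6 and 150.0 on 47 arrays and was 499 on the PR DG array of animal A25, close to targets of 150 and 500. With which program and settings the authors computed and scaled the deposited intensities, and whether they removed arrays, is not given in the sources used here.

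The number in a sample's title was read as the animal, since it recurs across the 3 layers of a treatment. The labels do not state this. It gave 9 CON and 8 PR animals. The numbers of 2 CON animals (A5 and A8) and 2 PR animals (A3 and A25) carry the prefix A, whose meaning is not given, and results are also given for animals with and without it. As a check of the pairing, deviations of the arrays from their group means were correlated over probe sets. The 46 pairs of arrays with the same number and different layers had a mean correlation of 0.160 (32 of 46 above 0.1, lowest -0.370). The 338 pairs with different numbers and different layers in the same treatment had -0.0204 (109 above 0.1). Deviations from a group mean cancel within the group, so the second mean is largely fixed by the first and is not an independent baseline.

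Of 15923 probe sets, 57 controls were left out of the tests. Arrays were quantile normalized, and a pseudocount of 11, the 20th percentile of the normalized values, was added before taking log2. The fold on the log2(value + pseudocount) scale understates changes of weakly expressed genes. A probe set was tested if it was above the 40th percentile of its own array on at least 7 arrays, the size of the smallest group, which kept 10800. This stands in for a measure of signal over background, since detection calls were not used here. The platform table names a gene for 13101 probe sets, 12789 of them a single gene and 312 several. Of the probe sets tested, 8929 had 1 gene, 228 several and 1643 none. Gene numbers of 12754 probe sets matched the reference table of gene symbols, and 0 symbols were changed by it.

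A linear model with 6 group means was fitted to each probe set with limma 3.58.1 in R 4.3.3, with the animal as a random block (consensus correlation 0.128) and moderated variances with an intensity trend. Contrasts were PR against CON in each layer, their mean over the 3 layers, the differences of the PR effect between layers, and the layers against each other in CON animals. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, and 0.05 was the threshold. For PR against CON the p-values rest on the spread between animals, with 7 to 9 arrays in a group. Contrasts between layers, and differences of the PR effect between layers, compare layers that mostly share animals. Their p-values rest largely on the spread between layers within animals. No sample had a repeat array, so the error of measurement was not separated from either spread. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

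Gene lists for 32 cell types and functions were written before the data were examined: CA1 markers, CA3 markers, dentate granule cell markers, astrocyte markers, microglia and macrophage markers, oligodendrocyte markers, endothelial and mural cell markers, interneuron markers, choroid plexus and ependymal markers, immediate early and activity-regulated genes, neuropeptides and granins, neurotrophic and growth factors, heat shock proteins and chaperones, endoplasmic reticulum stress response, antioxidant and metal-binding genes, apoptosis regulators, ionotropic glutamate receptors and partners, metabotropic glutamate receptors, GABA receptors and GABA handling, potassium channels, sodium, calcium and HCN channels, calcium-binding proteins and calcium handling, synaptic vesicle and exocytosis, oxidative phosphorylation, glycolysis and lactate, tricarboxylic acid cycle, proteasome and ubiquitin, cytosolic ribosomal proteins, cytoskeleton and axon growth, G protein signalling and adenosine, inflammation and interferon response and extracellular matrix. For each gene the probe set with the highest mean signal was used. Each list was tested against all other genes with the camera test on moderated t-statistics, once with a preset correlation of 0.01 between genes and once with the correlation estimated from the residuals. The fry test, which compares a list with no other genes, was run as well. Adjustment was over the 32 lists of a contrast. Counts of members past the threshold are given over all probe sets tested and, where stated, adjusted over the list alone.

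The rule for named genes was also fixed before the data were examined. For each PR contrast and each layer contrast it took the 8 largest rises and 8 largest falls among probe sets of a single named gene past the threshold, then up to 4 members of each list by size of change, and for differences between layers the 6 smallest p-values each way. Probe sets of several genes or none are counted and not named. Genes named in the overlap of the layers are a selection from the complete count, and members of that overlap outside the rule (Fn1, Grn, Cd81, Opa1, Podxl2, Cntnap2 and others) were named after their values were seen. Layer markers were looked at for every member as a check of the labels. Of 695 namings of 336 genes, 108 were of a gene with another tested probe set. In 15 of the namings another probe set had the opposite sign, and in 2 it was called with the opposite sign.

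The steps were tested on simulated data for PR against CON in DG, with 10800 probe sets, of which 200 were changed. Group sizes, the mean of each probe set over all arrays, its variance within groups and the correlation within animals came from the real arrays. Apart from the list shift given below, no other differences between groups were simulated. At a change of 0.5 on the log2 scale 60% of 80 were recovered, at 1 96.2% of 80, and at 2 100% of 40. Of 177 probe sets called, 12 had not been changed (6.78%). For the list test, a list was shifted by 0.3 in the PR CA1 arrays and tested for PR against CON in CA1. It was recovered, and 0 of 31 other lists were called. The probe sets were simulated independently of one another, while in the real data the estimated correlation within a list reached 0.492 (oligodendrocyte markers). The simulation thus does not tell how often the list test calls a list through correlation between its genes.

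Alternatives set before the data were examined were values as deposited, arrays centred on their medians, a pseudocount at the 5th percentile, no filter, a filter at the 60th percentile, no replicate block, the prefix A as a term, only animals without the prefix, array weights, and the replicate block as a fixed term for layers and differences between them. After the data had been seen, 4 were added: deposited values rescaled to 1 trimmed mean, no arrays of animal A25, no arrays high in Ttr, and the ratio of the 3' to the 5' probe set of GAPDH as a term. Also added then was the direction, in the prefix A animals, of calls made without them, for the probe sets tested in both, beside that of probe sets with p of at least 0.5 in the animals without the prefix. The 2 sets share no animal. No array was left out of the principal results.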

Results

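Gene expression was measured in 3 neuron populations of the rat hippocampus: the pyramidal neurons of CA1, the pyramidal neurons of CA3 and the granule cells of the dentate gyrus (DG). Total RNA from each sample was hybridised to 1 array, 48 arrays in all. The animals belonged to a control group (CON) or to a group the labels call PR. The groups held 9 arrays of CON CA1, 8 of CON CA3, 8 of CON DG, 8 of PR CA1, 7 of PR CA3 and 8 of PR DG, from 9 CON and 8 PR animals. The series concerns how susceptible neurons are to injury caused by seizures. The labels do not expand PR. The study is known to have compared rats preconditioned with a seizure with control rats, which is background about the study and not part of the labels. Each array gave an intensity for 15923 probe sets, of which 10800 passed the filter on dim signals and stood for 7856 named genes. Differences below are on the log2(intensity + pseudocount) scale, given with their standard error, and adjusted p-values come from limma. Changes called the largest are so on this scale, where the order of genes with weak signals depends on the pseudocount.

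The 3 populations were the main source of variation. The first principal component held 30.7% of the variance and set the dentate arrays apart from the pyramidal arrays. The second, with 16.1%, parted CA1 from CA3. Along the fourth component, with 5.64%, PR arrays scored from -23.3 to 0.31 and CON arrays from 2.90 to 16.6. The exception was the CA1 array of PR animal A25, which lay among the CON arrays at 3.36. Within groups, the median SD of a probe set on the log2 scale was 0.29 in CA1, 0.29 in CA3 and 0.24 in DG. The ratio of the 3' to the 5' probe set of GAPDH, a sign of RNA length, was 3.84 ± 0.74 (SD, n = 9) in CON CA1 and 3.39 ± 1.02 (SD, n = 8) in PR CA1 on the log2 scale. It was 2.83 ± 0.44 (SD, n = 8) in CON CA3 and 2.88 ± 0.38 (SD, n = 7) in PR CA3. In DG it was 3.36 ± 0.41 (SD, n = 8) in CON DG and 3.67 ± 0.59 (SD, n = 8) in PR DG.

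**Figure D1:**
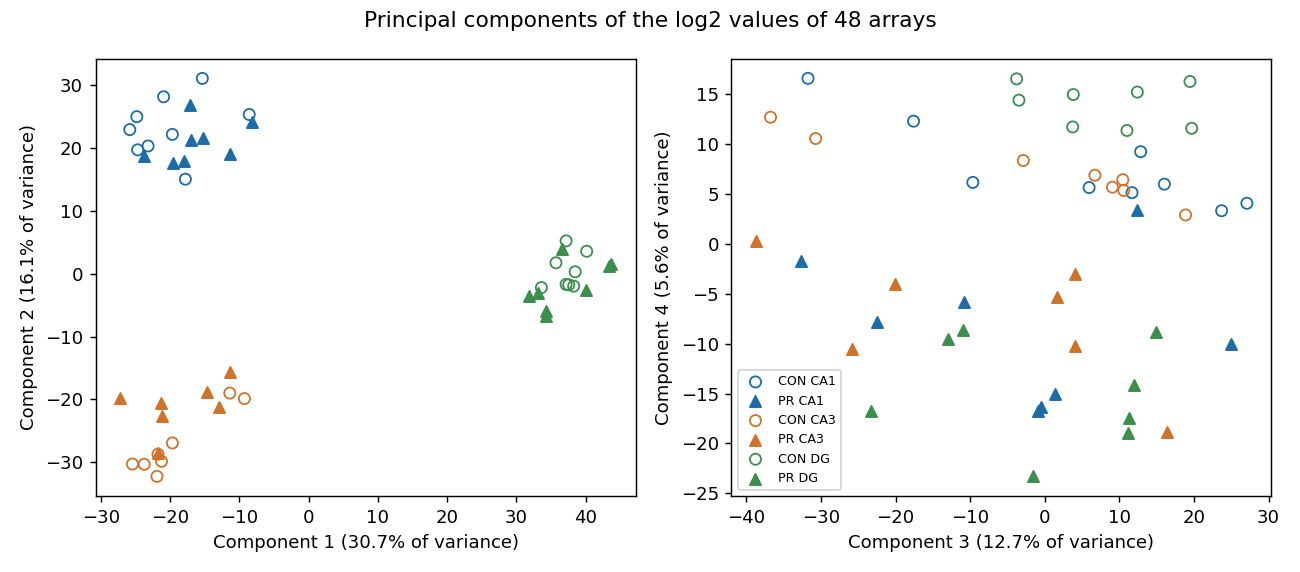
Scores of the 48 arrays on principal components 1 and 2 (30.7% and 16.1% of the variance) and on components 3 and 4 (12.7% and 5.64%), in log2 units, with CON arrays as open circles and PR arrays as filled triangles, CA1 in blue, CA3 in orange and DG in green. The first panel parts the 3 populations, and the fourth component parts PR from CON arrays except the CA1 array of PR animal A25.

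The first set of comparisons asked how the 3 populations differ in control animals. Between CA1 and CA3 (n = 9 and 8), CA1 was higher in Htr5b, a serotonin receptor (4.24 ± 0.21), in Pou3f1, a POU transcription factor (4.09 ± 0.22). It was also higher in Wfs1, the wolframin gene (3.39 ± 0.18), and in Fibcd1 (3.92 ± 0.26), Mpped1 (3.79 ± 0.17), Adgrl2 (3.45 ± 0.13), Olfm3 (3.29 ± 0.22) and Bhlhe41 (3.10 ± 0.12). CA3 was higher in Nnat, the imprinted gene of neuronatin (-4.30 ± 0.30 for CA1 minus CA3), in Grik4, a kainate receptor subunit (-3.44 ± 0.16). Kcna1, a voltage-gated potassium channel (-3.25 ± 0.32), was higher in CA3 too. Smco4 (-3.90 ± 0.17), Prss23 (-3.71 ± 0.24), Cst6 (-3.51 ± 0.24), Edil3 (-3.12 ± 0.21) and Pcp4 (-3.08 ± 0.33) were lower in CA1 as well. Bdnf, the brain-derived neurotrophic factor, was lower in CA1 (-2.73 ± 0.18). It was 1 of 11 neurotrophic and growth factors of the 22 measured that were lower in CA1, while 2 were higher (the same adjusted over the list alone, adjusted p = 0.0124). Inhbb, an inhibin subunit, was 1 of those higher members (2.38 ± 0.20). The call of this list was lost when the filter was set at the 60th percentile (adjusted p = 0.133). Of 25 genes of the synaptic vesicle and exocytosis, 17 were lower in CA1 and 1 was higher (the same adjusted over the list alone, adjusted p = 7.52e-06). Cplx2, Syn2 and Stx1a were among them (-2.35 ± 0.37, -1.54 ± 0.10 and -1.18 ± 0.15). The higher member was Slc17a6, a vesicular glutamate transporter (1.23 ± 0.29). In all, 2068 probe sets were higher and 1964 lower in CA1, the side with more calls being the same under each scaling. The GAPDH ratio also differed between CON CA1 (3.84) and CON CA3 (2.83). With this ratio as a term 3383 probe sets were called, of which 3012 were among the 4032 of the main fit with the same direction. Each of the 16 genes with the largest differences was on its side of the mean on 9 of 9 CA1 arrays.

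Between CA1 and DG (n = 9 and 8), CA1 was higher in Pou3f1 (5.36 ± 0.22), Gpr161 (5.34 ± 0.12), Vxn (5.20 ± 0.10) and Meis2 (5.09 ± 0.11). Mpped1 (5.09 ± 0.17), Wfs1 (4.68 ± 0.18), Ociad2 (4.65 ± 0.13) and Fibcd1 (4.64 ± 0.26) were higher in CA1 as well. DG was higher in Prox1, the homeobox gene that marks dentate granule cells (-4.70 ± 0.12 for CA1 minus DG), and in Pcp4, a calmodulin-binding protein (-4.67 ± 0.33). C11h21orf91 (-3.98 ± 0.31), Stxbp6 (-3.92 ± 0.21), Perp (-3.75 ± 0.13), Tiam1 (-3.75 ± 0.29), Medag (-3.71 ± 0.20) and Foxo1 (-3.65 ± 0.22) were lower in CA1 too. Of 26 immediate early and activity-regulated genes, 12 were higher in CA1 and 6 lower (12 higher and 7 lower adjusted over the list alone). The list passed at adjusted p = 0.0126 and was lost at adjusted p = 0.18 with an estimated correlation. Dusp6 (3.23 ± 0.21), Nr4a3 (2.36 ± 0.15) and Nr4a1 (2.06 ± 0.15) were higher and Jun (-2.77 ± 0.14) was lower. Homer1, a scaffold of glutamate receptors (1.72 ± 0.09), and Scn4b, an auxiliary sodium channel subunit (2.66 ± 0.11), were higher in CA1. Grm2, a metabotropic glutamate receptor (-2.84 ± 0.14), and Gabrd, a GABA-A receptor subunit (-1.56 ± 0.10), were lower. In all, 2097 probe sets were higher and 1993 lower in CA1. The larger side turned with the scaling, with 2386 higher and 1643 lower for median-centred arrays, 1182 higher and 1516 lower as deposited and 1809 higher and 2312 lower with deposited values rescaled to 1 trimmed mean.

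Between CA3 and DG (n = 8 and 8), CA3 was higher in Lpl, the lipoprotein lipase (4.73 ± 0.17), and in Meis2 (4.95 ± 0.12), Vxn (4.31 ± 0.10) and Prss23 (3.77 ± 0.25). Ociad2 (3.59 ± 0.13), Lats2 (3.44 ± 0.16), Nnat (3.41 ± 0.31) and Sulf2 (3.40 ± 0.11) were higher in CA3 too. DG was higher in Calb1, the calcium buffer calbindin (-4.45 ± 0.17 for CA3 minus DG), and in Prox1 (-4.84 ± 0.12), Perp (-3.87 ± 0.14) and H1f10 (-3.80 ± 0.54). Rreb1 (-3.77 ± 0.28), Zcchc12 (-3.76 ± 0.16), Rgs10 (-3.67 ± 0.13) and Ablim3 (-3.52 ± 0.10) were lower in CA3 as well. Of 28 cytosolic ribosomal protein genes, 24 were lower in CA3 and 0 higher (0 higher and 25 lower adjusted over the list alone, adjusted p = 9.21e-08, lost at adjusted p = 0.323 with an estimated correlation). Between CA1 and DG, 16 of the 28 were lower in CA1 (0 higher and 17 lower adjusted over the list alone, adjusted p = 0.000283, lost at adjusted p = 0.611 with an estimated correlation). Of 24 genes of glycolysis and lactate, 14 were higher in CA3 than in DG and 1 was lower (15 higher and 2 lower adjusted over the list alone, adjusted p = 0.00215, lost at adjusted p = 0.0583 with an estimated correlation). Ldha (1.44 ± 0.11), Pdha1 (1.23 ± 0.10) and Pfkfb3 (1.21 ± 0.13) were among the higher members. Between CA1 and CA3, 13 of the 24 were lower in CA1 and 3 higher (the same adjusted over the list alone, adjusted p = 0.0138, lost at adjusted p = 0.142 with an estimated correlation). This call was also lost with the GAPDH ratio as a term (adjusted p = 0.0566). Of the synaptic vesicle genes, 15 of 25 were higher in CA3 than in DG and 1 was lower (the same adjusted over the list alone, adjusted p = 0.00983, lost at adjusted p = 0.323 with an estimated correlation). The call was lost in the animals without prefix A as well (adjusted p = 0.0601). In all, 2672 probe sets were higher and 2572 lower in CA3. Here too it turned, with 2836 higher and 2367 lower for median-centred arrays, 1471 higher and 2083 lower as deposited and 2190 higher and 2899 lower with rescaled values.

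Layer markers chosen before the data were examined served to check the labels. All 10 measured CA1 markers were highest in CA1, 6 of 8 CA3 markers in CA3 and 10 of 11 granule cell markers in DG. The exceptions were Ociad2 and Fmo1, both highest in CA1, and Cald1. CA1 markers were higher in CA1 than in CA3, with a median of 2.88 (adjusted p = 3.17e-34), and than in DG, with a median of 3.99 (adjusted p = 1.20e-41). CA3 markers were lower in CA1 than in CA3 (adjusted p = 3.61e-05) and higher in CA3 than in DG (adjusted p = 6.33e-08). Granule cell markers were lower in CA1 than in DG (adjusted p = 1.90e-24) and lower in CA3 than in DG (adjusted p = 7.13e-26). CA1 markers were higher in CA3 than in DG (adjusted p = 0.00215), a call lost at adjusted p = 0.0583 with an estimated correlation. Of 14 interneuron markers, 7 were higher in CA1 than in CA3 and 0 lower (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0165, lost at adjusted p = 0.159 with an estimated correlation). Against DG, 8 were higher in CA1 and 2 lower (9 higher and 2 lower adjusted over the list alone, adjusted p = 0.0225, lost at adjusted p = 0.199 with an estimated correlation). The latter call was also lost with the filter at the 60th percentile (adjusted p = 0.0542). Cck, the cholecystokinin gene (1.61 ± 0.17 and 3.08 ± 0.17), was the member with the largest difference from DG. The animals without the prefix A gave 4087, 4036 and 5137 calls between CA1 and CA3, CA1 and DG, and CA3 and DG, and those with it 486, 727 and 1409. Of the calls made without the prefix A animals and measured in them, 76.5%, 88.2% and 76.5% had the same direction in the prefix A animals. Among probe sets with p of at least 0.5 it was 53.6%, 50.2% and 55.1%.

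**Figure D2:**
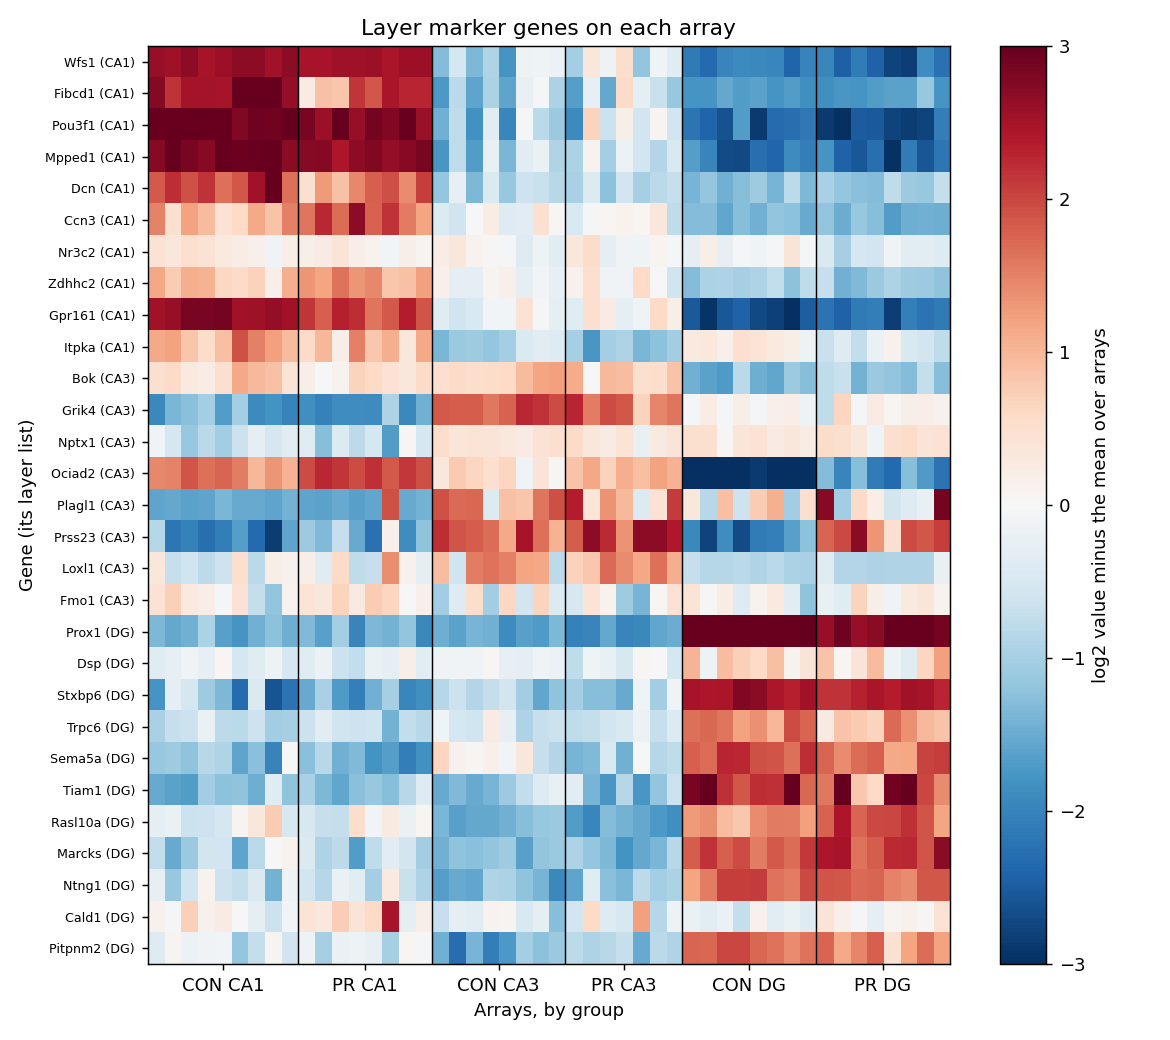
Heat map of the 29 measured layer markers (one line per gene) on each of the 48 arrays (columns), ordered by the 6 groups. Colour gives the log2 value on the array minus the mean over all 48 arrays. By the means of the CON groups, the 10 CA1 markers are highest in CA1, 6 of 8 CA3 markers in CA3 and 10 of 11 granule cell markers in DG.

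The next comparisons asked which transcripts differ between PR and CON animals in each population. In CA1 (8 PR and 9 CON arrays), Hspb1, a small heat shock protein, rose by 3.72 ± 0.39. Its intensity went from 5.81 ± 4.15 (SD, n = 9) in CON to 320.1 ± 290.4 (SD, n = 8) in PR. Mmp9, a secreted matrix metalloproteinase, rose by 3.50 ± 0.26, from 1.53 ± 0.311 (SD, n = 9) to 141 ± 63.4 (SD, n = 8). These were the 2 largest rises, in an order set by the pseudocount, since with it at the 5th percentile they were 4.85 and 5.31. Timp1, a tissue inhibitor of metalloproteinases, rose by 2.31 ± 0.27. The intermediate filament genes Vim (2.91 ± 0.39) and Gfap (2.25 ± 0.18), and the calcium-binding S100a4 (3.24 ± 0.27) rose as well. So did the galectin Lgals3 (2.16 ± 0.28) and Igfbp2, which binds insulin-like growth factors (1.98 ± 0.23). Egr2 (-2.02 ± 0.16), a zinc finger factor induced by neuronal activity as is Egr1 (-1.24 ± 0.16), had the largest fall. Arc, an activity-regulated gene of synaptic plasticity (-1.22 ± 0.17), and Rasd2, a small GTPase (-1.87 ± 0.32), fell as well. Boc, a co-receptor of hedgehog signalling (-1.46 ± 0.23), Fibcd1 (-1.32 ± 0.28), Fxyd7, a regulator of the sodium pump (-1.22 ± 0.19), and Htr5b (-1.11 ± 0.22) also fell. Adjusted p of these 16 genes ran from 3.68e-14 for Mmp9 to 0.00182 for Fibcd1.

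By group, 9 of 26 immediate early and activity-regulated genes fell in CA1 and 1 rose (the same adjusted over the list alone, adjusted p = 1.78e-10). The member that rose was Rgs2 (0.38 ± 0.11), a call lost under 6 of 13 alternatives (highest adjusted p = 0.544). Of 17 astrocyte markers, 6 rose and 0 fell (8 higher and 0 lower adjusted over the list alone, adjusted p = 1.78e-10). Beside Vim and Gfap, these included Fabp7, a fatty acid-binding protein (1.87 ± 0.23), and Clu, the clusterin gene (0.95 ± 0.23). Of 10 microglia and macrophage markers, 4 rose and 0 fell (6 higher and 0 lower adjusted over the list alone, adjusted p = 9.17e-06). The complement genes C1qa (0.96 ± 0.15) and C1qc (0.80 ± 0.18) were among them. With these glial markers higher, 4 of 17 inflammation and interferon genes rose and 0 fell (6 higher and 0 lower adjusted over the list alone, adjusted p = 8.14e-06). A2m, a protease inhibitor (0.94 ± 0.12), and B2m, of MHC class I (0.73 ± 0.17), were examples. Serpina3n, a serine protease inhibitor, rose by 1.53 ± 0.40, with 1553 on the array of PR animal 1 and 86.5 on the next highest PR array. Of 26 extracellular matrix genes, 6 rose and 1 fell (8 higher and 2 lower adjusted over the list alone, adjusted p = 2.04e-07). The rises included Mmp9, Timp1 and Col6a1, a collagen (1.17 ± 0.23). The fall was that of Dcn, the decorin gene (-0.71 ± 0.18), which did not pass with values as deposited (adjusted p = 0.0538). Of 19 neuropeptides and granins, 3 rose and 0 fell (4 higher and 0 lower adjusted over the list alone, adjusted p = 0.000334). They were Npy, the neuropeptide Y gene (1.53 ± 0.16), Trh, the thyrotropin-releasing hormone gene (1.06 ± 0.24), and Adcyap1 (0.73 ± 0.20). The call of Adcyap1 was lost under 5 of 13 alternatives (highest adjusted p = 0.164).

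A further 6 lists passed in CA1 with the preset correlation and not with an estimated one, all in the direction of higher values in PR. They were oligodendrocyte markers (0 of 14 rose, adjusted p = 0.012, adjusted p = 0.447 with an estimated correlation) and interneuron markers (1 of 14 rose, Npy, adjusted p = 0.0357, adjusted p = 0.248 with an estimated correlation). Antioxidant and metal-binding genes (4 of 22 rose, adjusted p = 0.0124, adjusted p = 0.107 with an estimated correlation) included Gpx1 (0.78 ± 0.16). Synaptic vesicle genes (0 of 25 rose, 5 adjusted over the list alone, adjusted p = 0.0255, adjusted p = 0.314 with an estimated correlation) were also among the 6. Glycolysis genes (2 of 24 rose, adjusted p = 0.0111, adjusted p = 0.107 with an estimated correlation) and ribosomal protein genes (0 of 28 rose, adjusted p = 0.00108, adjusted p = 0.436 with an estimated correlation) made up the rest. Each of these 6 except the oligodendrocyte list also lost its call under at least 1 alternative setting. The synaptic vesicle, glycolysis and ribosomal lists lost it with values as deposited, rescaled or median-centred (highest adjusted p = 0.182, 0.428 and 0.216), the first also without animal A25. The interneuron list lost it with rescaled values and in the animals without prefix A (highest adjusted p = 0.0666). The antioxidant list lost it with the GAPDH ratio as a term (adjusted p = 0.0522). Of single genes on other lists, the tubulin gene Tubb2b (1.18 ± 0.13), the calcium-binding S100a6 (1.25 ± 0.20) and the ryanodine receptor gene Ryr1 (1.07 ± 0.23) rose. Inhbb (-1.06 ± 0.21), Scn4b (-0.86 ± 0.12) and Kcnv1 (-0.68 ± 0.12) fell.

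In CA1, 237 probe sets were higher and 172 lower in PR out of 10800 tested. Counted by the probe set with the highest mean signal of each named gene, 322 genes passed. Of the 409, 64 differed by more than 2-fold. With values as deposited the split was 145 higher and 48 lower. Arrays centred on their medians gave 194 higher and 280 lower. Each of the 8 largest rises was above the CON mean on at least 7 of 8 PR arrays. The 8 largest falls were each below it on 8 of 8. On the CA1 array of PR animal A25, Hspb1 was 11.1 and Vim 7.63. Both lay within the CON ranges of 2.02 to 14.6 and 2.21 to 30.3. Among the 4 animals with the prefix A, limma called 0 probe sets (337 at an unadjusted p under 0.05). Among the other 13 animals it called 431. Of these calls 85.9% had the same direction in the prefix A animals, against 52.1% of probe sets with p of at least 0.5.

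In CA3 (7 PR and 8 CON arrays), Gfap rose by 3.07 ± 0.19 in PR, Hspb1 by 3.04 ± 0.41 and Trh by 2.64 ± 0.25. With the pseudocount at the 5th percentile these rises were 3.12, 4.50 and 3.53, so their order depends on it. Trh went from 10.6 ± 7.73 (SD, n = 8) to 124 ± 54.1 (SD, n = 7). Podxl2, a sialomucin (2.52 ± 0.33), S100a4 (2.47 ± 0.29), Vim (2.36 ± 0.42), Timp1 (2.01 ± 0.28) and the interferon-inducible Ifi27l2b (1.94 ± 0.16) rose as well. Rasd2 (-2.06 ± 0.35), Fxyd7 (-1.23 ± 0.21), Slc16a6, of the monocarboxylate transporter family (-1.20 ± 0.15), and Inhbb (-1.15 ± 0.23) had the largest falls. Scn4b (-1.07 ± 0.12), Boc (-1.01 ± 0.24), the annexin gene Anxa4 (-0.98 ± 0.17) and Jun, a subunit of the AP-1 transcription factor (-0.97 ± 0.16), followed. Adjusted p ran from 1.43e-16 for Gfap to 0.0113 for Boc. The call of Boc was lost in the animals without prefix A (adjusted p = 0.0898).

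Of 19 neuropeptides and granins, 4 rose in CA3 and 0 fell (6 higher and 0 lower adjusted over the list alone, adjusted p = 1.49e-08). Trh, Npy (1.45 ± 0.17) and the granin gene Scg2 (0.75 ± 0.10) were among them. Vgf, the fourth (0.93 ± 0.24), did not pass with values as deposited or without the prefix A animals (highest adjusted p = 0.112). Of 14 interneuron markers, 2 rose and 0 fell (the same adjusted over the list alone, adjusted p = 0.000276). Both were peptide genes, Npy and Tac3 (0.91 ± 0.23). Tac3 did not pass with values as deposited or without the prefix A animals (highest adjusted p = 0.0672). Of 17 astrocyte markers, 4 rose and 0 fell (5 higher and 0 lower adjusted over the list alone, adjusted p = 1.49e-08), with Gfap and Vim in the lead. Beside them, 3 of 17 inflammation and interferon genes rose and 0 fell (4 higher and 0 lower adjusted over the list alone, adjusted p = 0.0153). These were Timp1, A2m (0.67 ± 0.13) and Psmb8, a subunit of the immunoproteasome (0.50 ± 0.13). The inflammation call was lost without the prefix A animals (adjusted p = 0.0503), and Psmb8 under 4 of 12 alternatives (highest adjusted p = 0.529). Of 26 immediate early genes, 4 fell and 0 rose (0 higher and 7 lower adjusted over the list alone, adjusted p = 0.000311). They were Jun, Egr2 (-0.60 ± 0.17) and the nuclear receptor genes Nr4a3 (-0.83 ± 0.18) and Nr4a2 (-0.68 ± 0.17). Nr4a2 did not pass with values as deposited (adjusted p = 0.236) and Egr2 under 5 of 13 alternatives (highest adjusted p = 0.364). Of 20 sodium, calcium and HCN channel genes, 1 fell, Scn4b, and 0 rose (the same adjusted over the list alone, adjusted p = 0.0187). This list lost its call without the prefix A animals and with array weights (highest adjusted p = 0.0911).

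Of the lists that passed in CA3 with the preset correlation, 4 did not with an estimated one. Microglia markers (0 of 10 rose, 2 adjusted over the list alone, adjusted p = 0.0217, adjusted p = 0.281 with an estimated correlation) and oxidative phosphorylation (0 of 39 rose, adjusted p = 0.00206, adjusted p = 0.333 with an estimated correlation) were higher. The others were ribosomal proteins (0 of 28 rose, adjusted p = 2.18e-06, adjusted p = 0.281 with an estimated correlation) and extracellular matrix genes (3 of 26 rose, adjusted p = 0.0239, adjusted p = 0.252 with an estimated correlation). The microglia list lost its call without the prefix A animals and with array weights (highest adjusted p = 0.0883), and the matrix list with array weights (adjusted p = 0.0877). In all, 111 probe sets were higher and 66 lower in PR in CA3, with 39 of the 177 over 2-fold. Counted by the probe set with the highest mean signal of each named gene, 141 genes passed. Each of the 16 largest changes was on its side of the CON mean on 7 of 7 PR arrays. On the CA3 array of PR animal A25, Hspb1 was 18.2 against at most 4.97 on a CON array, and Vim 16.6 against at most 28.6. Without the prefix A animals limma called 307 probe sets, of which 60.7% had the same direction in the prefix A animals, against 48.6% of probe sets with p of at least 0.5. The prefix A animals gave 0 calls (724 at an unadjusted p under 0.05). With values as deposited 57 passed.

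In DG (8 PR and 8 CON arrays), Prss23, a serine protease, rose by 3.81 ± 0.27 in PR and Hspb1 by 3.71 ± 0.40, or by 4.14 and 5.36 with the pseudocount at the 5th percentile. Lox, the lysyl oxidase that cross-links collagen and elastin, rose by 3.27 ± 0.16, from 33.3 ± 8.2 (SD, n = 8) to 428 ± 134 (SD, n = 8). 6330403K07Rikl (3.20 ± 0.14), Lgals3 (3.15 ± 0.29), Vim (3.12 ± 0.40), Nnat (3.10 ± 0.33) and S100a4 (3.10 ± 0.28) rose as well. Gpc3, a cell-surface glypican, had the largest fall (-2.82 ± 0.19), from 137 ± 35.7 (SD, n = 8) to 10.1 ± 5.66 (SD, n = 8). The transcription factor gene Rreb1 (-2.19 ± 0.30), the chemokine gene Cxcl12 (-2.15 ± 0.23), and Ddit4l, an inhibitor of mTOR signalling (-2.02 ± 0.12), also fell. Spata13 (-1.98 ± 0.21), Boc (-1.97 ± 0.23), the interleukin receptor gene Il6r (-1.95 ± 0.25) and the neurotrophin gene Ntf3 (-1.94 ± 0.25) were lower too. Adjusted p of these genes ran from 9.01e-24 for 6330403K07Rikl to 2.17e-07 for Rreb1.

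Of 19 neuropeptides and granins, 7 rose in DG and 0 fell (8 higher and 1 lower adjusted over the list alone, adjusted p = 2.00e-08). They included Trh (2.22 ± 0.25) and Npy (1.69 ± 0.16), Penk, the proenkephalin gene (1.97 ± 0.18), and the prohormone convertase gene Pcsk2 (0.93 ± 0.16). Calcium-binding and calcium-handling genes were lower than other genes, with 9 of 35 falling and 3 rising (6 higher and 10 lower adjusted over the list alone, adjusted p = 0.0297). The median of the list was -0.14, but 0.08 with values as deposited. Ryr1 (-1.51 ± 0.23), the inositol trisphosphate receptor gene Itpr1 (-1.47 ± 0.14) and Calb1 (-1.44 ± 0.18) were among the falls, and S100a10 rose (1.34 ± 0.20). This list lost its call under 4 of 13 alternatives: as deposited, median-centred, with the filter at the 60th percentile and without the arrays high in Ttr (highest adjusted p = 0.0925). Of 17 inflammation and interferon genes, 4 rose and 0 fell (5 higher and 0 lower adjusted over the list alone, adjusted p = 0.00233). These were Timp1 (1.82 ± 0.27), A2m (0.93 ± 0.13), the transcription factor gene Stat3 (0.84 ± 0.23) and B2m (0.59 ± 0.17). The call of B2m was lost under 3 of 13 alternatives (highest adjusted p = 0.115). Beside them, 7 of 17 astrocyte markers rose and 0 fell (10 higher and 1 lower adjusted over the list alone, adjusted p = 2.63e-05, lost at adjusted p = 0.13 with an estimated correlation). Gfap (2.10 ± 0.19), Aqp4 (0.92 ± 0.25) and Clu (0.90 ± 0.23) rose next to Vim. Of 8 measured CA3 markers, 2 rose and 0 fell (the same adjusted over the list alone, adjusted p = 2.63e-05): Prss23 and Ociad2 (1.42 ± 0.14).

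Some lists moved both ways in DG. The immediate early genes did not pass as a list (adjusted p = 0.399), with 4 rising and 5 falling of 26 (5 higher and 7 lower adjusted over the list alone). Nr4a3 (-1.55 ± 0.17) and Fos (-1.30 ± 0.24) fell, while Ptgs2, the inducible cyclooxygenase (1.25 ± 0.18), and Fosb (0.98 ± 0.18) rose. Of 22 neurotrophic and growth factors, 3 rose and 4 fell (the same adjusted over the list alone, adjusted p = 0.422). Bdnf rose (1.37 ± 0.20), while Ntf3 and Gdf10 (-1.67 ± 0.16) fell. GABA receptor and handling genes had 1 rise and 3 falls of 14 (the same adjusted over the list alone, adjusted p = 0.327). The receptor subunit genes Gabra5 (-0.81 ± 0.13) and Gabrd (-0.74 ± 0.11) fell and Gabrb2 (0.56 ± 0.12) rose. Gabrd did not pass with values as deposited (adjusted p = 0.0519) nor Gabrb2 with median-centred arrays (adjusted p = 0.128). Potassium channel genes had 3 rises and 1 fall of 26 (the same adjusted over the list alone, adjusted p = 0.344). The fall was that of Kcnip2, an auxiliary subunit of A-type channels (-1.47 ± 0.17). The mixed fry test, of change in either direction, gave adjusted p = 2.83e-19, 1.52e-11, 4.35e-05 and 0.000103 for these 4 lists in turn. This test compares a list with no other genes. In DG 16 of 32 lists passed it, and 10.6% of all probe sets tested were called. Of 26 extracellular matrix genes, 5 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.116). Bgn, the biglycan gene (1.83 ± 0.30), and Mmp9 (1.67 ± 0.27) rose and Sparcl1 fell (-1.01 ± 0.10).

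In DG, 595 probe sets were higher and 554 lower in PR. Counted by the probe set with the highest mean signal of each named gene, 862 genes passed. Of the 1149, 188 differed by more than 2-fold. With values as deposited, where 1 PR DG array was on another scale and the median of all probe sets lay at 0.22, the split was 902 higher and 118 lower. Median-centred arrays gave 428 higher and 554 lower. Each of the 16 largest changes was on its side of the CON mean on 8 of 8 PR arrays. Limma called 1035 probe sets without the prefix A animals and 24 among them. Of the former 90.6% had the same direction in the prefix A animals, against 52% of probe sets with p of at least 0.5. Ttr, a transcript abundant in choroid plexus, was 1986 on the DG array of PR animal 1, 1047 on that of PR animal 15 and 1218 on the CA3 array of CON animal A8. Its median over all arrays was 29.8. On the DG array of PR animal A25, Hspb1 was 109 and Vim 130, within the range of the other PR DG arrays.

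**Figure D3:**
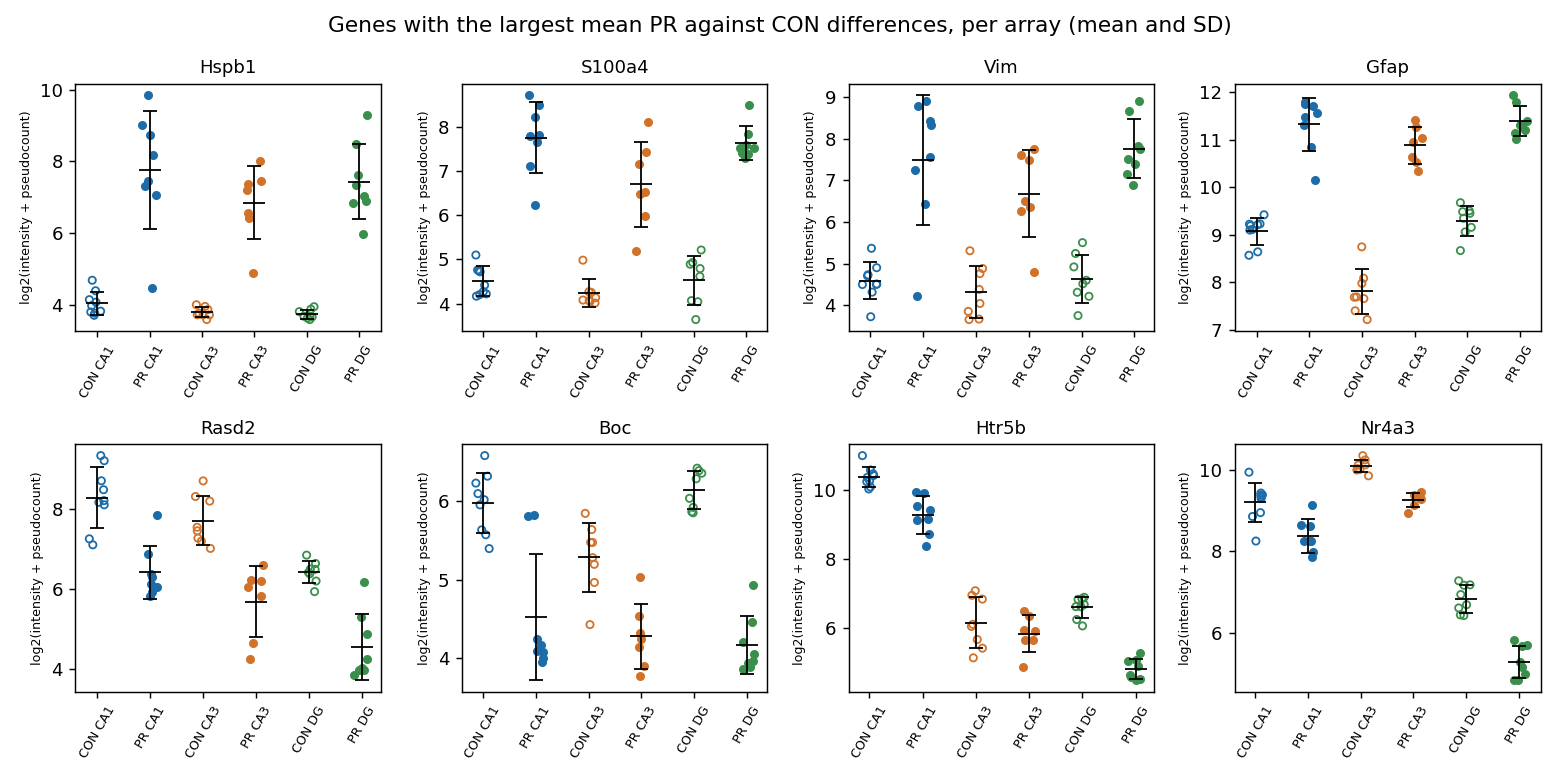
Values per array of 8 genes, chosen by the mean PR minus CON difference over the 3 populations. Hspb1, S100a4, Vim and Gfap have the largest rises, and Rasd2, Boc, Htr5b and Nr4a3 the largest falls. The vertical axis gives log2(intensity + pseudocount) and the horizontal axis the 6 groups, with points for arrays and bars for the group mean and SD. Hspb1 shows the largest rise over the 3 layers, 3.49 ± 0.26.

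For changes shared by the populations, the mean of the 3 PR minus CON differences was tested (23 PR and 25 CON arrays). Hspb1 (3.49 ± 0.26), S100a4 (2.94 ± 0.18), Vim (2.79 ± 0.26) and Gfap (2.47 ± 0.12) had the largest rises. Lgals3 (2.28 ± 0.19), 6330403K07Rikl (2.25 ± 0.09), Timp1 (2.05 ± 0.18) and Mmp9 (2.00 ± 0.17) followed. Rasd2 (-1.94 ± 0.22), Boc (-1.48 ± 0.15), Htr5b (-1.08 ± 0.15), Nr4a3 (-1.07 ± 0.11) and Fxyd7 (-1.05 ± 0.13) had the largest falls. The Wnt ligand gene Wnt4 (-1.04 ± 0.17), Cxcl12 (-1.02 ± 0.15) and Egr2 (-1.01 ± 0.10) fell as well. In all, 552 probe sets were higher and 479 lower, with 48 of the 1031 over 2-fold on average. Each of the 8 rises was above the CON mean on at least 22 of 23 PR arrays and each of the 8 falls below it on at least 21. The split with values as deposited was 546 higher and 99 lower. Median-centred arrays gave 414 higher and 562 lower. Limma called 1235 without the prefix A animals and 4 among them. The same direction was found in the prefix A animals for 73.6% of the former, against 46.9% of probe sets with p of at least 0.5.

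The set called in each of the 3 populations separately held 38 probe sets higher in PR, where independent lists of these sizes would share 0.134, and 9 lower, against 0.0539. In 99 other splits of the animals, the highest number in common was 0 in both directions. By the probe set with the highest mean signal of each gene, 35 named genes were higher in all 3 layers. They included Hspb1, Gfap, Vim, Npy, Trh, Timp1, A2m, Lgals3, S100a4, Igfbp2, Aqp4 and Podxl2. Also in this set were the fibronectin gene Fn1, the progranulin gene Grn, the tetraspanin gene Cd81 and Opa1, of mitochondrial fusion. Fn1 lost its call in CA3 under 4 of 13 alternatives (highest adjusted p = 0.292), and another probe set of Aqp4 in CA3 had the opposite sign. The 7 named genes lower in all 3 were Boc, Cntnap2, Ddit3, Fxyd7, Nr4a3, Rasd2 and Scn4b. Ddit3, a transcription factor of the endoplasmic reticulum stress response, fell by 0.54 ± 0.09 on average. Its call in CA1 was lost under 5 of 13 alternatives (highest adjusted p = 0.647), and in CA3 and DG with values as deposited (adjusted p = 0.315 and 0.235). In pairs of layers, 54 probe sets were higher in both CA1 and CA3 (2.44 for independent lists), 116 in CA1 and DG (13.1) and 49 in CA3 and DG (6.12). The lower sets shared 18 (1.05), 51 (8.82) and 20 (3.39). In turn 3, 18 and 6 were called in opposite directions. The layers of an animal are not independent, and the values for independent lists leave this out.

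Over the mean of the layers, 8 lists passed with both correlations. Astrocyte markers (10 of 17 rose, 0 fell, 10 higher and 1 lower adjusted over the list alone, adjusted p = 7.03e-13) and microglia markers (5 of 10 rose, 0 fell, adjusted p = 8.60e-05) were higher in PR. So were the inflammation genes (6 of 17 rose, 0 fell, adjusted p = 5.15e-06) and extracellular matrix genes (8 of 26 rose, 1 fell, adjusted p = 6.28e-05). Higher as well were neuropeptides and granins (7 of 19 rose, 0 fell, adjusted p = 4.90e-12) and CA3 markers (2 of 8 rose, 0 fell, adjusted p = 0.00229). Immediate early genes were lower (9 of 26 fell, 3 rose, 3 higher and 14 lower adjusted over the list alone, adjusted p = 9.24e-06), with Fos (-0.85 ± 0.15) and Arc (-0.77 ± 0.11) as further examples. Sodium, calcium and HCN channels were lower too (2 of 20 fell, 0 rose, adjusted p = 0.0219), a call lost with array weights and without the arrays high in Ttr (highest adjusted p = 0.0575). The median of these channels was -0.05, and 0.03 with values as deposited. That of glycolysis genes, below, was 0.07, and -0.00746 with median-centred arrays. Another 5 lists passed with the preset correlation alone. Oligodendrocyte markers (1 of 14 rose, adjusted p = 0.00816, adjusted p = 0.475 with an estimated correlation) and endothelial and mural markers (1 of 7 rose, adjusted p = 0.0484, adjusted p = 0.171 with an estimated correlation) were among these. Interneuron markers (2 of 14 rose, adjusted p = 0.00246, adjusted p = 0.0517 with an estimated correlation) also passed this way. The others were glycolysis genes (6 of 24 rose, adjusted p = 0.013, adjusted p = 0.101 with an estimated correlation) and ribosomal proteins (1 of 28 rose, adjusted p = 0.00617, adjusted p = 0.485 with an estimated correlation). The endothelial list lost its call under 4 of 13 alternatives (highest adjusted p = 0.0758), glycolysis under 3 (highest adjusted p = 0.171) and ribosomal proteins with median-centred arrays (adjusted p = 0.0916).

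The other 19 lists did not pass over the mean of the layers. The members that rose and fell were 0 and 1 of 10 for CA1 markers (adjusted p = 0.62), 0 and 1 of 11 for dentate granule cell markers (adjusted p = 0.582) and 1 and 0 of 8 for choroid plexus and ependymal markers (adjusted p = 0.237). They were 2 and 3 of 22 for neurotrophic and growth factors (adjusted p = 0.829), 3 and 1 of 27 for heat shock proteins and chaperones (adjusted p = 0.746) and 0 and 2 of 22 for endoplasmic reticulum stress response (adjusted p = 0.15). For further lists they were 4 and 0 of 22 for antioxidant and metal-binding genes (adjusted p = 0.141), 0 and 1 of 19 for apoptosis regulators (adjusted p = 0.898) and 1 and 1 of 23 for ionotropic glutamate receptors and partners (adjusted p = 0.247). The numbers were 0 and 0 of 5 for metabotropic glutamate receptors (adjusted p = 0.141), 0 and 2 of 14 for GABA receptors and GABA handling (adjusted p = 0.428) and 2 and 2 of 26 for potassium channels (adjusted p = 0.811). Next came 4 and 9 of 35 for calcium-binding proteins and calcium handling (adjusted p = 0.084), 4 and 0 of 25 for synaptic vesicle and exocytosis (adjusted p = 0.152) and 1 and 0 of 39 for oxidative phosphorylation (adjusted p = 0.733). Those left were 0 and 0 of 18 for tricarboxylic acid cycle (adjusted p = 0.829) and 1 and 0 of 32 for proteasome and ubiquitin (adjusted p = 0.178), and 3 and 4 of 30 for cytoskeleton and axon growth (adjusted p = 0.898) and 3 and 4 of 36 for G protein signalling and adenosine (adjusted p = 0.758). The median and the mean of the list differed in sign for CA1 markers, neurotrophic factors, heat shock proteins, GABA genes and G protein signalling. For apoptosis regulators the test pointed down while both were above 0. Of the 32 lists, 12, 10, 5 and 13 passed in CA1, CA3, DG and the mean with the preset correlation. With an estimated correlation 6, 6, 4 and 8 of them held. In the layer comparisons 6, 5 and 6 passed and 4, 2 and 2 held for CA1 and CA3, CA1 and DG, and CA3 and DG. The fry test, of whether the genes of a list move on balance one way, passed for 11, 7, 16 and 15 lists in CA1, CA3, DG and the mean. The mixed fry test, of change in either direction, did for 10, 9, 16 and 18. Neither fry test compares a list with other genes.

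**Figure D4:**
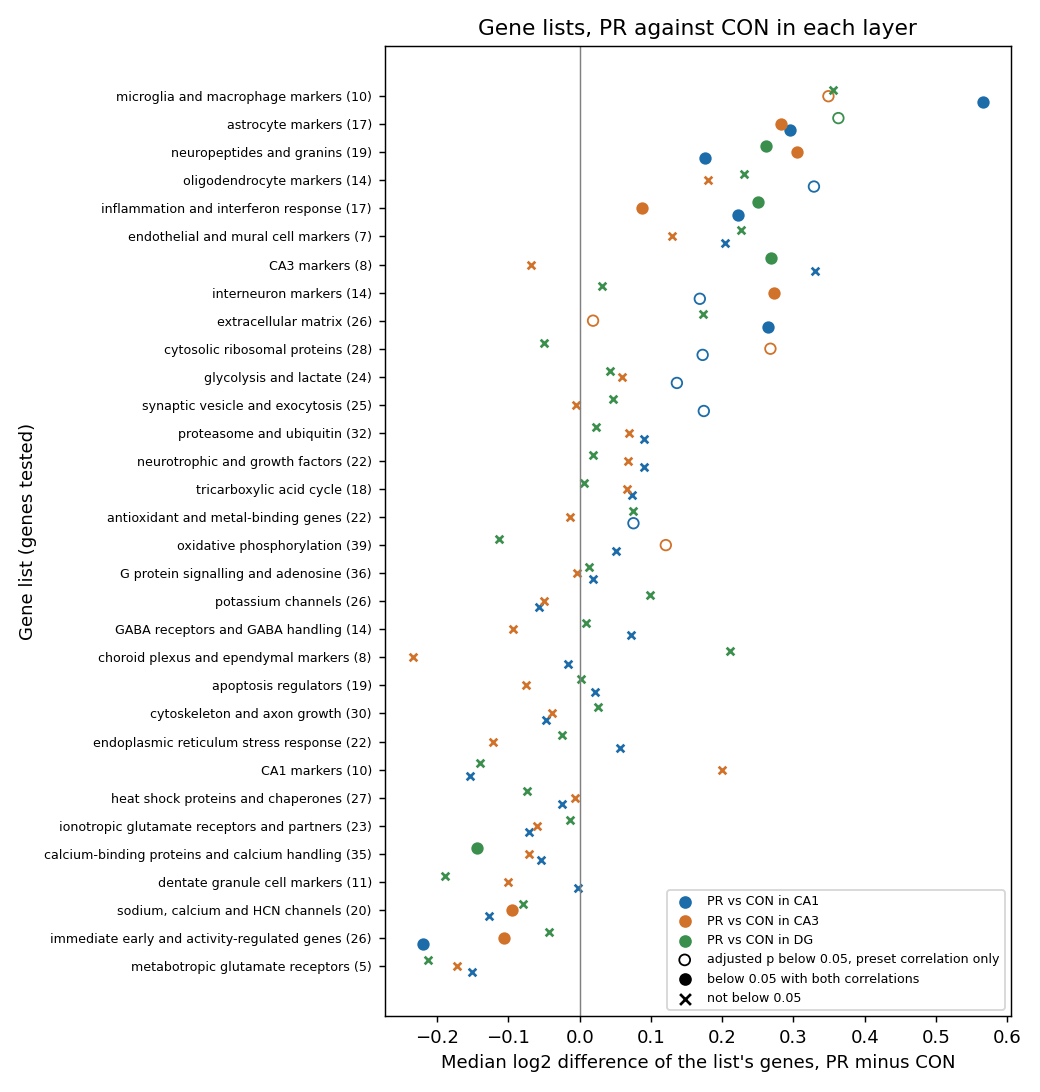
Median log2 difference between PR and CON (horizontal axis) of each of the 32 gene lists (vertical axis) in CA1, CA3 and DG, with filled symbols for lists that passed with the preset and with an estimated correlation, open symbols for the preset alone and crosses for lists that did not pass. Neuropeptides and granins and the inflammation list have filled symbols in all 3 layers, and the immediate early list in CA1 and CA3.

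The last comparisons tested whether the PR minus CON difference itself differs between populations. Between CA1 and CA3, Mmp9 (2.67 ± 0.35), Anxa4 (1.83 ± 0.23) and Igfbpl1 (1.46 ± 0.24) had a higher difference in CA1. So had Col12a1 (1.00 ± 0.19), Ddah1 (0.90 ± 0.17) and Arhgdib (0.76 ± 0.15). Irf9, a transcription factor of interferon signalling (-1.19 ± 0.17), and Egr2 (-1.42 ± 0.21) had a lower one. Ifi27l2b (-1.22 ± 0.20), Kcnv1 (-0.85 ± 0.16), Gpr161 (-0.93 ± 0.18) and Shb (-1.10 ± 0.22) did too. Col12a1, Ddah1, Arhgdib, Ifi27l2b, Kcnv1, Gpr161 and Shb did not pass with values as deposited (adjusted p from 0.0515 to 0.304), and of these Gpr161 and Shb also not without the prefix A animals. The test called 21 probe sets higher and 25 lower, 866 having an unadjusted p under 0.05. The split was 5 and 3 with values as deposited and 18 and 36 with median-centred arrays. It was 29 and 22 with deposited values rescaled to 1 trimmed mean. Of the 32 lists 7 passed, and 0 held with an estimated correlation. They were CA1 markers (2 of 10 lower, adjusted p = 0.0102, adjusted p = 0.155 with an estimated correlation) and choroid plexus markers (adjusted p = 0.0301, adjusted p = 0.263 with an estimated correlation). Immediate early genes (adjusted p = 0.0301, adjusted p = 0.264 with an estimated correlation) and endoplasmic reticulum stress genes (adjusted p = 0.0388, adjusted p = 0.155 with an estimated correlation) were among the 7. The others were antioxidant genes (adjusted p = 0.0212, adjusted p = 0.155 with an estimated correlation), synaptic vesicle genes (adjusted p = 0.0351, adjusted p = 0.408 with an estimated correlation) and extracellular matrix genes (adjusted p = 0.0301, adjusted p = 0.263 with an estimated correlation). All of these lists but that of CA1 markers also lost their call under at least 1 alternative, with the highest adjusted p = 0.895 for the matrix genes, and synaptic vesicle genes under 9 of 14 alternatives.

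Between CA1 and DG, the PR minus CON difference was higher in CA1 for Gpc3 (2.99 ± 0.25), Spata13 (2.36 ± 0.27) and Ddit4l (2.24 ± 0.16). For Cdh13 (1.64 ± 0.17), Sparcl1 (1.28 ± 0.12) and Igfbp5 (1.96 ± 0.22) it was higher there too. It was lower for Lox (-3.13 ± 0.21) and for Tmem71 (-1.97 ± 0.21), Agrn (-1.68 ± 0.17), Cyb561 (-1.67 ± 0.16), Frmd6 (-1.63 ± 0.18) and Dkk3 (-1.46 ± 0.14), of which Agrn encodes the matrix proteoglycan agrin. Between CA3 and DG it was higher in CA3 for Gpc3 (2.82 ± 0.26), Ddit4l (2.09 ± 0.16), Gdf10 (1.83 ± 0.21), Cdh13 (1.64 ± 0.18), Mal2 (1.56 ± 0.19) and Sparcl1 (1.11 ± 0.13). It was lower in CA3 for Lox (-3.41 ± 0.22), Prss23 (-3.25 ± 0.36), Rprm (-2.99 ± 0.33), Sln (-1.93 ± 0.20), Frmd6 (-1.54 ± 0.18) and Dkk3 (-1.31 ± 0.14). The CA1 and DG test called 238 probe sets higher and 231 lower, and the CA3 and DG test 222 and 223. With values as deposited these were 48 and 167 and 39 and 175, where the median of all probe sets lay at -0.19 and -0.22. Median-centred arrays gave 182 higher and 203 lower for the former and 222 higher and 159 lower for the latter. CA3 markers had a lower PR difference in CA1 than in DG (adjusted p = 0.00637) and in CA3 than in DG (adjusted p = 0.000888), again through Prss23 and Ociad2. Between CA1 and DG, 4 more lists passed with the preset correlation alone. They were immediate early genes (adjusted p = 0.00267, adjusted p = 0.1 with an estimated correlation) and neuropeptides (adjusted p = 0.0114, adjusted p = 0.143 with an estimated correlation). The others were oxidative phosphorylation (adjusted p = 0.0114, adjusted p = 0.686 with an estimated correlation) and ribosomal proteins (adjusted p = 0.0109, adjusted p = 0.755 with an estimated correlation). These 2 were lost under 5 of 14 alternatives and 4 of 14 alternatives (highest adjusted p = 0.541 and 0.231). Their medians were 0.18 and 0.19, but -0.10 and -0.08 with values as deposited. Between CA3 and DG, those that passed this way were oxidative phosphorylation (adjusted p = 0.000142, adjusted p = 0.435 with an estimated correlation) and ribosomal proteins (adjusted p = 0.000741, adjusted p = 0.553 with an estimated correlation). For CA1 and CA3, CA1 and DG, and CA3 and DG the prefix A animals by themselves gave 0 (506 at an unadjusted p under 0.05 in limma), 4 and 4 calls, and the others 44, 436 and 375. Of the latter calls 78.8%, 87.6% and 91.9% had the same direction in the prefix A animals, against 48.3%, 50.7% and 50.6% of probe sets with p of at least 0.5.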

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

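All tests of the Gfap and Vim pattern below were chosen only after the result was seen, and those of the other patterns before, although Hspb1, Vim and Gfap on the arrays of animal A25 and the median of the CA3 list in DG had been seen by then. The counts of other splits were planned.

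A value is given here where 1 array of a group lay farther from the nearest other array, in proportion to the range of the group, than Dixon's 95% limit allows. Of 1216 such tests over 336 named genes and the scaling, 74 (6.09%) met this. Chance alone gives about 1 in 20 groups, so the number is close to what chance gives. Values are intensities after normalization, with the nearest other array of the group in brackets.

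In CON CA1 (9 arrays) single arrays stood apart as follows. Animal A5 was highest in Bdnf (98, next 54), Stat3 (77.3, next 48.5), Tnr (141, next 71.5), Perp (10.6, next 4.03) and Tiam1 (20.9, next 8.9) and lowest in Olfm3 (269, next 624). Animal 3 was highest in Cst6 (55.6, next 34.5) and lowest in Penk (116, next 181), Map2 (719, next 1007) and Bhlhe41 (1076, next 1475). Animal A8 was lowest in C1qc (5.95, next 20.5) and Rpl27 (369, next 676). Animal 26 was lowest in S100a6 (2.45, next 8.95) and Spata13 (6.95, next 24.9). Animal 6 was lowest in Gnb5 (789, next 1203) and Rgs5 (8.17, next 19.7). Animal 13 was highest in Idh2 (389, next 284) and lowest in 6330403K07Rikl (318, next 482). Animal 10 was lowest in Cryab (24.4, next 49.5).

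In CON CA3 (8 arrays) single arrays stood apart as follows. Animal A5 was highest in S100a4 (20.6, next 8.31), Atp2b1 (2784, next 2580) and Perp (3.14, next 1.79). Animal 19 was highest in Rprm (33.4, next 22.4) and lowest in Txnip (10.2, next 32.3). Animal 22 was lowest in Plagl1 (16.2, next 53.5). Animal 3 was lowest in Chgb (2281, next 2628). Animal A8 was lowest in Sucla2 (773, next 1091). Animal 10 was lowest in Atf4 (369, next 502).

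In CON DG (8 arrays) single arrays stood apart as follows. Animal 22 was lowest in Fabp7 (446, next 901), Slc2a3 (184, next 272), Frmd6 (24, next 34.5), Psme1 (83.5, next 119), Perp (106, next 158) and Per1 (17.2, next 70.2). Animal 13 was highest in Mmp9 (12.9, next 3.19) and lowest in Cxcl12 (565, next 753). Animal 10 was highest in Stmn4 (849, next 595) and lowest in Grm6 (5.45, next 15.1). Animal A5 was highest in Meis2 (1.81, next 1.04) and lowest in Lox (16, next 29.9). Animal A8 was highest in Lats2 (114, next 87.4) and lowest in Pfkm (469.9, next 565).

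In PR CA1 (8 arrays) single arrays stood apart as follows. Animal A25 was highest in Egr2 (79, next 32.1) and lowest in C1qc (23.5, next 46.8), Tac3 (31.2, next 79.7) and Pfkp (525, next 784). Animal 9 was highest in Lox (63.1, next 31.4), Gpc3 (39.3, next 3.48) and Cxcl12 (149.8, next 80.9). Animal 1 was highest in Serpina3n (1553, next 86.5) and lowest in Kcnip4 (5.98, next 18.8). Animal 4 was lowest in Txn1 (1395, next 1739). Animal 11 was lowest in Ndufa5 (56.3, next 138). Animal A3 was highest in Kcnip3 (352, next 247).

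In PR CA3 (7 arrays) single arrays stood apart as follows. Animal 4 was highest in Jun (256, next 170.2) and Gpc3 (9.52, next 4.18) and lowest in Timp2 (23.3, next 52.3) and Igfbpl1 (0.618, next 11.4). Animal 1 was highest in Serpina3n (299, next 59) and lowest in Ntf3 (12.8, next 63.4) and Kcnip4 (3.8, next 17.6). Animal 9 was highest in B2m (939, next 450.3) and Uqcrh (2394, next 1810) and lowest in Atp2b1 (1111, next 1947). Animal A25 was lowest in C1qc (14.8, next 25.1).

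In PR DG (8 arrays) single arrays stood apart as follows. Animal 1 was highest in S100a4 (348, next 218), Igfbp2 (163, next 72.9) and Serpina3n (183, next 35.9) and lowest in Homer1 (183, next 247) and Idh3b (234, next 319). Animal A25 was lowest in A2m (51.3, next 71.9). Animal A3 was highest in Fosb (178, next 105). Animal 11 was highest in Cidea (46.5, next 37.1).

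Serpina3n was highest on the arrays of PR animal 1 in all 3 layers. The trimmed mean as deposited was 499 on the PR DG array of animal A25, with 150 on the nearest other array of the group.

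PR effects differed between layers by the test of the difference itself. Between CA1 and CA3, 46 probe sets passed, and the genes with the smallest p were higher in CA1 for Anxa4 (1.83), Mmp9 (2.67), Igfbpl1 (1.46), Col12a1 (1.00), Ddah1 (0.90) and Arhgdib (0.76) and lower for Irf9 (-1.19), Egr2 (-1.42), Ifi27l2b (-1.22), Kcnv1 (-0.85), Gpr161 (-0.93) and Shb (-1.10). Between CA1 and DG, 469 passed, with a higher effect in CA1 for Ddit4l (2.24), Gpc3 (2.99), Sparcl1 (1.28), Cdh13 (1.64), Igfbp5 (1.96) and Spata13 (2.36) and a lower one for Lox (-3.13), Dkk3 (-1.46), Cyb561 (-1.67), Agrn (-1.68), Tmem71 (-1.97) and Frmd6 (-1.63). Between CA3 and DG, 445 passed, with a higher effect in CA3 for Ddit4l (2.09), Gpc3 (2.82), Cdh13 (1.64), Sparcl1 (1.11), Gdf10 (1.83) and Mal2 (1.56) and a lower one for Lox (-3.41), Sln (-1.93), Dkk3 (-1.31), Rprm (-2.99), Prss23 (-3.25) and Frmd6 (-1.54).

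Each count was set against other splits of the animals into groups of the same sizes, 100 splits with the real one. Few splits reached the real count, and these numbers include the real split and were not adjusted for the number of counts. In CA1 3 of 100 splits gave at least the real 409 (highest other 1141). In CA3 4 gave at least 177 (highest other 2712) and in DG 1 gave 1149 (highest other 210). For the mean of the layers 3 gave at least 1031 (highest other 1804). For the differences between layers it was 1 for CA1 and CA3 (46, highest other 3), 1 for CA1 and DG (469, highest other 36) and 2 for CA3 and DG (445, highest other 1257). With layers reassigned within CON animals it was 1, 1 and 1, with 4032, 4090 and 5244 real calls and at most 1569, 709 and 2457 in another assignment. For the counts with 1, no other split reached the real one. A chance split is not excluded in CA1, CA3, the mean and the CA3 and DG difference, nor is a structure of the samples other than PR. In each of these another split called more probe sets than the real one. These splits parted the animals along the first axis of variation within groups, which held 28.4% of that variance, by 1.33, 1.76, 1.51 and 1.25 SD, where the median of the other splits was 0.281, 0.383, 0.288 and 0.347 and the highest 1.18, 1.35, 1.23 and 1.39. For the CA3 and DG difference another split thus lay farther along this axis, which does not single out the split with most calls.

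The first pattern weighed was the rise of Gfap and Vim in PR in all 3 layers. More astrocyte RNA in the PR samples would raise other astrocyte markers by about as much as Gfap, but the median rise of the other 15 members was 0.24 on the log2 scale (quartiles -0.03 and 0.50), with Gfap at 2.47 and 1 in 4 parts of its rise at 0.62. Of these 15 members 8 passed as higher and 0 as lower, so a smaller addition of astrocyte RNA is not excluded. Scaling of the arrays is not the source, since Gfap rose by at least 2.41 under 3 other scalings. What stays open, as a hypothesis found and tested on the same data, is a higher expression of these filament genes with PR, in astrocytes within the samples or elsewhere.

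The second pattern was animal A25, whose CA1 array showed Hspb1 (11.1) and Vim (7.63) at the level of CON arrays and whose CA3 array showed Vim (16.6) at that level, while Gfap was 1127 and 1289, above every CON array. A wrong label would put the array among the CON arrays, but over the probe sets called without this animal it showed a median share of the PR difference of 0.351 in CA1 and 0.702 in CA3, with at most 0.143 and 0.219 on a CON array and 0.668 and 0.680 as the lowest on other PR arrays. A swap with a CON array would need such an array with the PR difference, and the highest share on a CON array of CA1 or CA3 was 0.219. In DG the share on the A25 array was 0.670, with 0.749 as the lowest of the other PR arrays. The probe sets were chosen on the CON and the other PR arrays, which favours low shares on the former and high shares on the latter. The A25 arrays had no part in the choice. Both ranges may thus be too narrow, and the CA1 share of 0.351 lay between them. The ratio of the 3' to the 5' probe set of GAPDH on the A25 CA1 array was 4.76 on the log2 scale. It was the highest of all 48 arrays, with 4.74 on the next, the CA1 array of CON animal 13. The same ratio of beta-actin was 4.30 on the A25 CA1 array, close to the PR CA1 mean of 4.24. A weaker response of this animal stays open. Neither this nor a part of RNA length in the CA1 share was tested.

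The third pattern was the rise of CA3 markers in PR DG, which rests on 2 called members, Prss23 and Ociad2. CA3 tissue in the PR DG samples would add a common share of the CA3 level of all genes enriched in CA3. Over the 14 genes more than 8-fold higher in CA3 than DG, however, the median share gained was 0.0124 (quartiles -0.00975 and 0.151). The 2 called members, themselves among the 14, needed a median of 0.608, from unlike values of 1.06 for Prss23 and 0.157 for Ociad2. The value of Ociad2 lay close to the upper quartile, so the comparison bears on Prss23 and says little about Ociad2. The CON DG arrays enter both comparisons. With these arrays split the median effect of the list was 0.19 and 0.34, but the list was not chosen with these arrays, so this test decides nothing. Of the 14 genes, Lpl and Meis2 gained -0.00347 and 0.00364 of their CA3 level, but Nnat, Rem2 and Man1a1, not among the called members, 0.876, 0.278 and 0.135. The share was below 0 for 6 of the 14, among them Nr4a3 at -0.0791, which fell in PR DG (-1.55 ± 0.17). A higher expression with PR in DG of some genes enriched in CA3, not of Prss23 and Ociad2 alone, stays open as a hypothesis found and tested on the same data.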

How the results depend on the processing

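The rescaled deposited values, the fits without animal A25 or without the arrays high in Ttr, and the fit with the GAPDH ratio were chosen after the data had been seen. No named gene changed sign and no list test changed direction, relative to other genes, under any alternative. The median of a list itself changed sign for 4 results with values as deposited and for glycolysis genes over the mean with median-centred arrays, as given with the results. Over all alternatives, named genes kept direction and side of the threshold 8993 times and lost the threshold 362 times, gene lists 892 and 75 times, and counts stayed within 1.5 times 134 times and moved beyond 15 times. Of 695 results of named genes 539 and of 72 list results 46 held throughout. The deposited values, where 1 PR DG array is on another scale, ended the most calls of named genes (117), and the animals without the prefix A and median centring the most list calls (11 each). The filter at the 60th percentile gave no value for genes it removed. Weak signals limit the data, since detection calls were not used here and a change in a gene near the pseudocount is understated.

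With values as deposited the count of calls was 193 for PR in CA1 (against 409), 57 for PR in CA3 (against 177), 645 for the mean of the layers (against 1031), 8 for the difference between CA1 and CA3 (against 46), 215 for that between CA1 and DG (against 469), 214 for that between CA3 and DG (against 445), 2345 for CA1 against CA3 (against 4032) and 2698 for CA1 against DG (against 4090). With the deposited values rescaled to 1 trimmed mean, which in effect changes the scale of the PR DG array of animal A25 alone, they were 439, 172, 1034, 51, 424, 418, 3950 and 4121 in turn, all within 1.5 times, so the scale of this array accounts for the lower counts. With array weights it was 851 for PR in CA1 (against 409), 421 for PR in CA3 (against 177), 1763 for the mean of the layers (against 1031), 84 for the difference between CA1 and CA3 (against 46), 779 for that between CA1 and DG (against 469) and 756 for that between CA3 and DG (against 445), and in the animals without prefix A 307 for PR in CA3 (against 177), for which the cause was not tested. Median centring kept the counts within 1.5 times and moved the split in CA1 to 194 higher and 280 lower. The larger side also turned with scaling in DG, the mean, the differences between layers and the layers against DG, as given with the results. Without the prefix A animals the split was 498 higher and 537 lower in DG, and 46% of the calls were higher over the mean. Array weights gave 856 higher and 907 lower over the mean, and leaving out the arrays high in Ttr 465 higher and 471 lower in DG. In the differences between layers, where the sides are close to equal, it turned under further settings. The other counts stayed within 1.5 times under every setting.

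Without the replicate block the counts were 400 for PR in CA1, 186 for PR in CA3, 1141 for PR in DG, 1447 for the mean of the layers, 33 for the difference between CA1 and CA3, 359 for that between CA1 and DG, 341 for that between CA3 and DG, 3634 for CA1 against CA3, 3777 for CA1 against DG and 4846 for CA3 against DG, and with it as a fixed term 44 for the difference between CA1 and CA3, 457 for that between CA1 and DG, 429 for that between CA3 and DG, 3985 for CA1 against CA3, 4070 for CA1 against DG and 5195 for CA3 against DG. Leaving out the block ended 12 calls of named genes and 0 of lists, and the fixed term 2 and 0. The fixed block gave 25 higher and 19 lower for the difference between CA1 and CA3.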

Other observations

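Further members of the lists changed over the mean of the layers. Among potassium channel genes, the A-type channel partner Kcnip2 fell (-0.72 ± 0.11), while Kcnip3 (0.62 ± 0.13) and the background channel gene Kcnk2 (0.40 ± 0.11) rose. Among calcium-binding genes S100a10 (1.10 ± 0.13), S100a6 (0.97 ± 0.13) and Rcan2 (0.68 ± 0.09) rose and Itpr1 fell (-0.59 ± 0.09). The small heat shock protein gene Cryab, of the same family as Hspb1, rose (0.52 ± 0.14), and so did the matrix genes Bgn (1.17 ± 0.19) and Lum (0.69 ± 0.16). The regulator of G protein signalling Rgs14 rose in CA1 (0.78 ± 0.18) and over the mean (0.49 ± 0.12).

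Genes enriched in a layer were looked at in PR after the values were seen, with the CON arrays of the layer split so that 1 part chose the genes and the other gave the effect. In DG, 68.7% and 69.7% of the 182 and 175 enriched genes were lower in PR in the 2 splits (median -0.28 and -0.28 on the log2 scale), with 50.6% and 49.6% of the other genes. In CA1 it was 63.3% and 62.9% of 90 and 97 genes (median -0.09 and -0.12), and in CA3 56.8% and 60.9% of 74 and 69 (-0.08 and -0.05). The genes are not independent of one another and no p-value was computed.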
